A study of Mus musculus with 75 samples.

How the data were processed

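Ribosome-bound RNA from the visual cortex of 8-week-old C57BL/6 mice was profiled in 75 samples, 5 Cre lines by 5 housing conditions by 3 replicates. Each replicate was a pool of the visual cortices of 3 mice. Per the labels, RNA was immunopurified on HA-tagged ribosomes, amplified by SPIA (a linear method for small amounts of RNA) and sequenced as single-end 50-bp reads. The deposited table gives 1 normalized signal per gene and library, made by the authors as gene read counts divided by a factor per library; the file states no unit. TopHat2 2.0.13, Bowtie2 2.1.0.0, Cuffnorm, Cuffdiff 2.2.1, BWA and the mm9 build are named in the submitters' processing notes, which give neither their order nor their settings. Alignments, duplicates and multiply mapped reads were not examined here, and no coordinates are printed because the annotation at hand (GRCm38) is of another build. The unit was read from the values. Within a library, 92.8 to 96.6% of the values worth up to 20 reads were whole multiples of 1 step, within a tolerance of 0.1 read, and the step (the worth of 1 read) was 0.422 to 3.40. Libraries summed to 20.6 to 24.9 M after normalization. Dividing by the step gave depths of 7.28 to 52.3 M gene reads (median 24.8).

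Before the data were examined, the design assumed FPKM, and its settings were kept as written for the values found. The table held 14284 genes, of which 23 named as dates by a spreadsheet were dropped, leaving 14261. Columns of 2 samples (SST dark replicate 2 and SST standard replicate 2) were empty, so 73 libraries were used and those 2 groups have n = 2. The other 23 groups have n = 3. Means over replicates are given by the file in 25 columns, and these lay within 0.00864% of the means computed from the libraries. Some genes stood at 0 in single libraries while the median of the others was at least 50 reads. Such genes were set aside within a line, after this was seen (17 in Emx, 12 in Gad2, 15 in PV, 11 in SST and 37 in VIP, 54 in the fit of all lines). Genes were kept with a signal of at least 1 in at least 3 libraries of the fit. Repeat libraries of a group varied far beyond counting error (chi-square per degree of freedom at least 19.0) and correlated at 0.905 to 0.983 on the log2 scale, so replicates, not depth, set the precision of abundant genes.

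Each line was fitted by itself with limma 3.58.1 in R 4.3.3 (statmod 1.5.0) on log2(signal + 1), with robust, trended moderation and a 5% false discovery rate (Benjamini-Hochberg) in each contrast. Each light time and standard housing was compared with dark housing, giving 20 contrasts. Lines were compared in 1 fit of all groups, with an absolute log2 difference of at least 1 as a further requirement. The 3 inhibitory classes were each set against the other two, and Emx against Gad2. A differing light response was tested as the interaction of line and light time, jointly over the 3 times. Fold changes are 2 to the power of the fitted log2 difference. All tests were two-sided except that for shared calls, a one-sided Fisher exact test. Spreads are SD over replicates. Genes named by rule are the 6 largest rises and 4 largest falls among the calls of each contrast, and 6 for each comparison of lines. Igf1 and 6 marker genes (Slc17a7, Gad2, Pvalb, Sst, Vip, Emx1) were named in each comparison of lines, and Igf1 in every contrast. Of the genes so named, 1 is not reported here. A list is illustrated by its members with the largest change among those called. Other members were chosen after their values were seen where the text says so.

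Fixed lists were tested with camera at a preset correlation of 0.01, and again with an estimated correlation. The 14 gene lists were immediate early transcription factors, early activity-regulated effectors, activity-regulated secreted factors, IGF and insulin signalling, neuropeptides, excitatory synapse, inhibitory synapse, perineuronal net and matrix, voltage-gated potassium channels, circadian clock, heat shock and unfolded protein response, cholesterol synthesis, oxidative phosphorylation and cytosolic ribosomal proteins. A further 10 lists held markers of excitatory, inhibitory, PV, SST and VIP neurons, astrocytes, oligodendrocytes, their precursors, microglia and macrophages, and endothelial cells and pericytes. Adjusted p-values of lists cover all lists of a kind over the 20 contrasts.

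No label says what the replicate number marks, so it was checked whether it pairs the samples. After the mean of each condition was removed from genes with a mean of at least 50, every library lay nearest to libraries of its own number in its line. The number held 98.0, 99.7, 99.4, 99.3 and 87.2% of the variance of the leading component in Emx, Gad2, PV, SST and VIP. The profile of a number also recurred across lines (median r over 11896 genes of 0.848, 0.582 and 0.829 for numbers 1, 2 and 3; genes are not independent replicates). Numbers thus mark a structure shared by the samples, such as a processing batch, and each fit was repeated with the number as a block. The fits without it are the ones chosen before the data were examined, and blocked values stand beside them.

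The procedure was tested on simulated data built on these libraries, with 100 changed genes per size for the contrasts with the dark, 200 for levels between lines and 94 to 100 for differing responses. For the contrasts with the dark and the differing responses, the data carried the replicate-number effects and the spread of the blocked fits. A higher recovery with the block was thus built in and does not tell which fit suits the real data better. Without the block, limma recovered 56, 68, 41, 36 and 33% of genes changed 2-fold and 93, 97, 86, 88 and 77% of those changed 4-fold in Emx, Gad2, PV, SST and VIP, and called 0 to 2 unchanged genes. With the block the shares were 92, 91, 86, 82 and 52% and 100, 99, 97, 99 and 89%, with 7 to 12 unchanged genes called. Limma voom on the recovered reads gave 56, 64, 37, 34 and 28% and 93, 92, 81, 80 and 66%. Between lines, 99.5 to 100% of 4-fold differences were recovered. The interaction test recovered 82.1, 90.6, 84.0 and 80% of 4-fold differences in response (PV, SST, VIP, and Emx against Gad2) and called 4, 1, 35 and 1 unchanged genes. Its blocked form called 61, 46, 543 and 11 unchanged genes, so blocked counts of differing responses are overstated, for VIP most of all. With a spread fitted for each line, 2, 3, 6 and 7 unchanged genes were called.

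Alternatives fixed before the data were examined were a pseudocount of 0.1, no filter, rescaling by median ratios, the replicate block, a spread pooled over all lines, an estimated correlation and leaving out each library in turn. Added after seeing the data were voom, a filter of at least 50, keeping the genes set aside, a spread for each line, the block together with an estimated correlation, and leaving out VIP standard replicate 3, a library with 9.08 M reads and 815 genes at 0 that correlated least with its group. The 6 libraries of each contrast were split in all 10 ways into 3 and 3, and 100 random draws were made for the comparisons of lines. A further 100 draws for differing responses, which dealt the conditions only among libraries of one line and replicate number, were added after seeing the data. Figures were drawn with python 3.11.15 and matplotlib 3.10.9.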

Results

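Light was given to dark-housed adult mice to ask which genes each class of cortical neuron changes in response to visual experience. The series title names Igf1 in VIP neurons. The RiboTag method tags ribosomes with an epitope in cells that express Cre recombinase, so that the RNA bound to them can be pulled out of whole tissue. The Cre lines were Emx (active in excitatory neurons of the cortex), Gad2 (inhibitory neurons in general), PV, SST and VIP, the last 3 marking separate classes of inhibitory neuron. Mice were kept in standard housing, in the dark, or in the dark followed by 1 h, 3 h or 7.5 h of light. Each group held 3 pools of 3 mice, except that 2 libraries were used in SST dark and in SST standard. Those 2 groups lack replicate number 2, which the SST light groups hold. Without the block, a change with light in SST therefore also carries a difference between replicate numbers. Depth was 33.2 ± 9.18 M gene reads in dark libraries (mean ± SD, n = 14), 30.4 ± 8.05 at 1 h and 30.1 ± 9.03 at 3 h (n = 15 each). It was lower at 7.5 h (14.6 ± 5.26, n = 15) and in standard housing (16.2 ± 6.48, n = 14), and ranged from 7.28 to 52.3 M over the 73 libraries. Gene levels are normalized read counts, as mean ± SD over the libraries of a group.

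Each line was rich in the RNA of its own neuron class. Slc17a7, the vesicular glutamate transporter of cortical excitatory neurons, stood at 23451 ± 4023 in the Emx line (n = 15) and at 1102 to 4236 in the other lines. Emx1, the gene whose promoter names the line, stood at 266 ± 76.5 there, and Gad2, a synthase of GABA, at 45193 ± 4664 in the Gad2 line against 421 in Emx. Pvalb reached 11942 ± 4412 in the PV line (n = 15), 10221 in Gad2, 1250.0 in SST and 146 in VIP. Sst reached 84433 ± 11122 in the SST line (n = 13), 50950.5 in Gad2, 931 in PV and 1047 in VIP. Vip reached 81843 ± 22281 in the VIP line (n = 15), 7512 in Gad2, 267 in SST and 71.8 in PV. The Emx libraries also held glial RNA. Their median log2 level was 11.51 for 10 astrocyte markers and 11.53 for 10 oligodendrocyte markers, close to the 11.87 of 14 excitatory neuron markers, and 9.75 for 6 precursor markers, so a change in the Emx line cannot be assigned to neurons alone. Inhibitory markers had a median of 5.91 there and of 12.82 to 13.26 in the 4 inhibitory lines. VIP libraries held more RNA of other cells than PV libraries did, with medians of 9.94 against 8.69 for excitatory, 8.96 against 7.37 for astrocyte and 6.83 against 5.05 for endothelial markers. Microglia markers were highest in the Gad2 line (8.70, against 5.10 in Emx). These medians were not tested. With Slc17a7 at 1102 to 4236, the inhibitory lines too held some RNA of excitatory neurons. A rise there of a gene more abundant in Emx thus cannot be assigned to the tagged class alone.

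After 1 h of light all 5 lines raised the transcription factors that neuronal activity induces within minutes. The Emx line changed 91 genes (89 higher, 2 lower; 404 with the block, 313 higher). Egr2, a zinc finger factor, rose from 180.1 ± 205 to 5228 ± 458 (44.5-fold, log2 5.47, SE 0.57, adjusted p = 8.38e-05). It was followed by Atf3 (25.3-fold), Fos (21.1-fold), Npas4 (20.2-fold), Fosb (17.8-fold) and Egr4 (13.5-fold). Pkdrej fell (log2 fold change -1.55). In the Gad2 line 31 genes (31 higher, 0 lower; 181 with the block, 161 higher) changed. Fosb, a partner of Jun in AP-1, led with a rise from 90.4 ± 31.0 to 3179 ± 810.2 (35.5-fold, log2 5.15, SE 0.32, adjusted p = 1.80e-06). Then came Npas4 (28.9-fold), Fos (28.5-fold), Egr2 (21.5-fold), Nr4a1 (16.8-fold) and Nr4a3 (16.2-fold). The PV line changed 22 genes (22 higher, 0 lower; 77 with the block, 73 higher). Npas4, a factor restricted to depolarized neurons, rose 52.0-fold (adjusted p = 5.35e-05) and Fos from 65.6 ± 18.1 to 2803 ± 696 (42.3-fold, log2 5.40, SE 0.21, adjusted p = 1.61e-09). Behind them were Egr2 (31.7-fold), Fosb (26.7-fold), Nr4a3 (23.4-fold) and Nr4a1 (17.1-fold). In the SST line 46 genes (46 higher, 0 lower; 194 with the block, 169 higher) changed. Egr2 rose there from 26.4 ± 17.6 to 2581 ± 911 (102-fold, log2 6.67, SE 0.43, adjusted p = 3.31e-06), ahead of Fosb (78.9-fold), Npas4 (59.3-fold), Egr4 (42.6-fold), Fos (37.4-fold) and Nr4a1 (37.1-fold). The VIP line changed 41 genes (41 higher, 0 lower; 84 with the block, 83 higher). Their largest rise was that of Fosb, from 135 ± 52.7 to 8416 ± 3005 (62.2-fold, log2 5.96, SE 0.38, adjusted p = 3.41e-07), and Npas4 (47.2-fold), Egr2 (43.6-fold), Fos (26.5-fold), Nr4a3 (19.3-fold) and Nr4a1 (17.8-fold) came after it.

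Of 109 genes raised in any line at 1 h, 16 were raised in all 5: Arc, Dusp1, Egr1, Egr2, Egr3, Egr4, Fos, Fosb, Fosl2, Junb, Npas4, Nr4a1, Nr4a2, Nr4a3, Sik1 and Tiparp (38 with the block). Lines shared far more calls than chance gives, for example 30 between SST and VIP where 0.133 were due by chance (Fisher exact test, adjusted p = 3.97e-70). This test takes genes as independent, which they are not, so its p-values here and below are too small. Among the 20 immediate early transcription factors 17, 14, 12, 15 and 13 rose in Emx, Gad2, PV, SST and VIP. They were 20, 19, 17, 20 and 18 when adjusted over the list alone. Median log2 changes of the list were 2.95, 2.48, 2.53, 3.90 and 3.21. It was called in each line (adjusted p = 4.81e-05 to 2.99e-04 with an estimated correlation). Of the 20 early effectors, which include the cytoskeletal gene Arc, phosphatases of the Dusp family and the kinase Sik1, 17, 6, 5, 11 and 11 rose (19, 17, 13, 19 and 17 adjusted over the list alone; adjusted p = 8.33e-05 to 0.00101 with an estimated correlation). Arc rose 10.1-fold in Emx, 11.1-fold in Gad2, 7.75-fold in PV, 24.5-fold in SST and 8.63-fold in VIP. Over all genes, 609 of 14189 (PV at 1 h) to 2670 of 14193 (Emx at 7.5 h) had no overlap between the libraries of the 2 groups in contrasts of 3 against 3. Chance would give 10% if the 6 libraries were exchangeable, which their pairing by replicate number speaks against. Called genes were all among the genes without overlap, which their selection by a test on the same libraries all but fixes. Leaving out 1 library moved the counts to 49 to 81 (Emx), 16 to 26 (Gad2), 16 to 20 (PV), 25 to 36 (SST), 20 to 45 (VIP). The fall of Pkdrej in Emx lost its call (adjusted p up to 0.134).

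**Figure D1:**
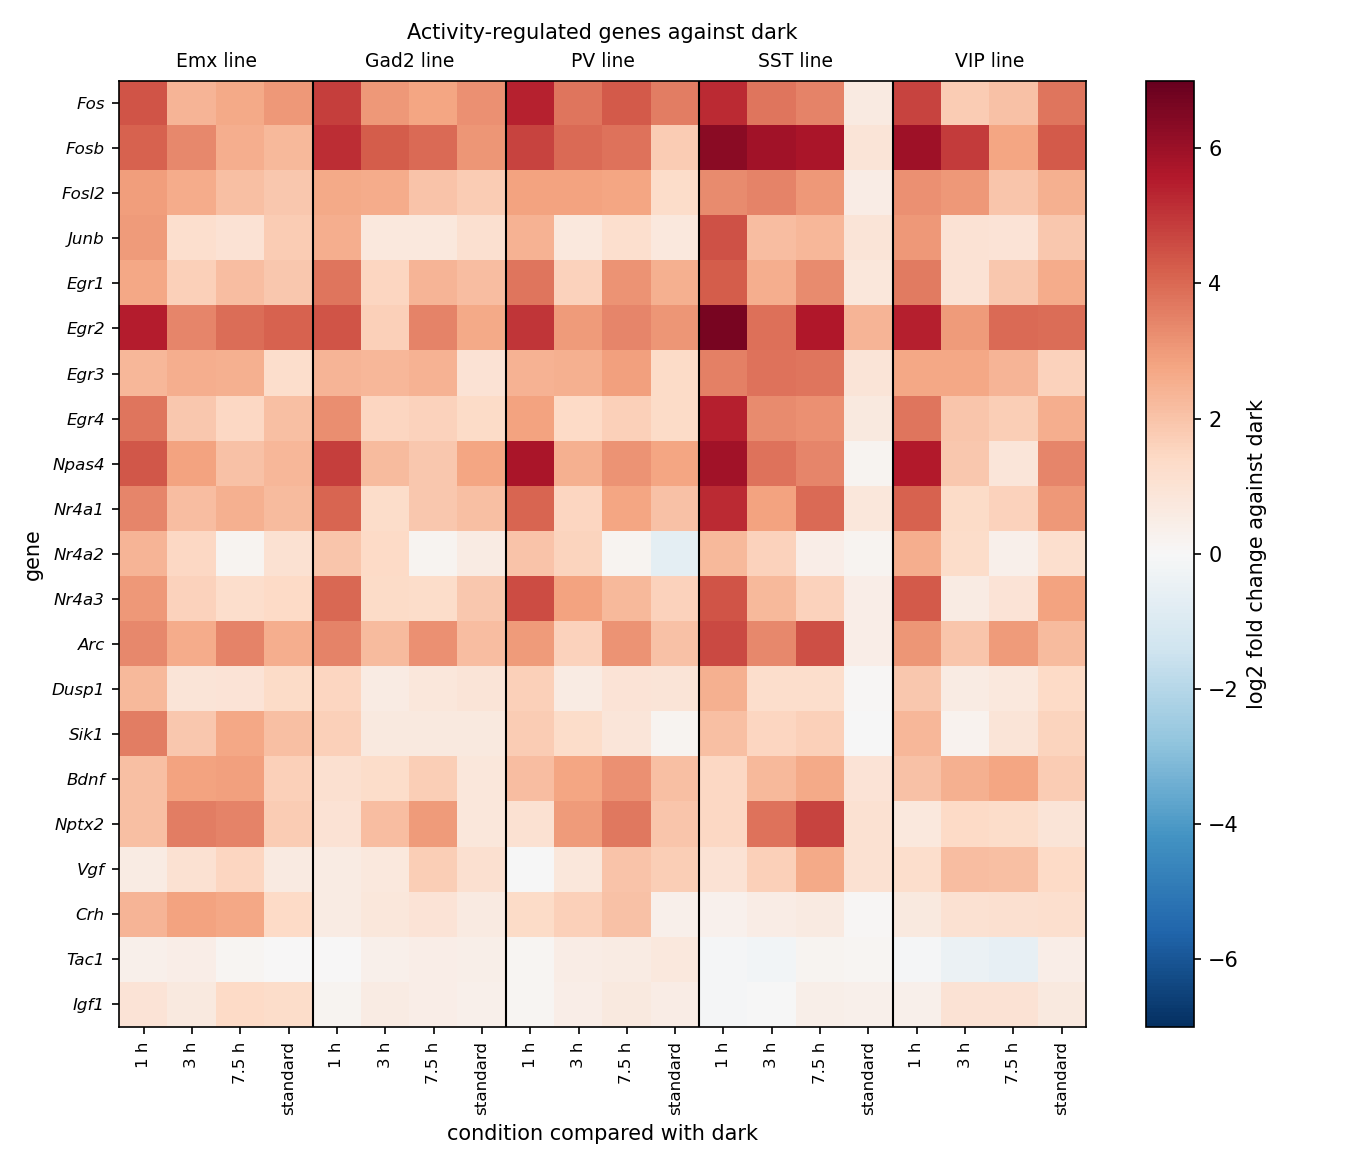
Log2 fold change against dark housing (colour, ending at 7 in either direction) of activity-regulated genes, by Cre line and by 1 h, 3 h and 7.5 h of light and standard housing. Fosb at 1 h ranges from 4.15 in Emx to 6.30 in SST, and Nptx2 at 7.5 h from 1.26 in VIP to 4.76 in SST.

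At 3 h of light Nptx2 was among the largest rises in the Emx, PV and SST lines. Emx libraries changed in 152 genes (138 higher, 14 lower; 1739 with the block, 1043 higher). Nptx2, a secreted pentraxin that clusters AMPA receptors, rose from 319 ± 18.4 to 3849 ± 725 (11.9-fold, log2 3.57, SE 0.22, adjusted p = 1.02e-06) . Inhba, an activin subunit, rose from 105 ± 47.0 to 1306 ± 245 (12.98-fold, log2 3.70, SE 0.43, adjusted p = 4.25e-04). Also among their largest rises were Timp1 (16.1-fold), Baz1a (11.6-fold), Egr2 (10.6-fold) and Fosb (10.5-fold). The largest falls were Slc22a3 (-1.76), Col8a1 (-1.60), 4932411E22Rik (-1.57) and Ankfn1 (-1.49) in log2. The Gad2 line changed 18 genes (18 higher, 0 lower; 442 with the block, 338 higher). Its leading genes were Fosb (18.7-fold), Fos (8.13-fold), Cdkn1a (6.24-fold), Fosl2 (6.12-fold), Egr3 (4.97-fold) and Arc (4.69-fold). Cdkn1a is an inhibitor of cyclin-dependent kinases. In the PV line 11 genes (11 higher, 0 lower; 140 with the block, 123 higher) changed, of which Fosb (15.6-fold), Fos (13.2-fold), Egr2 (7.83-fold), Nptx2 (7.80-fold), Nr4a3 (7.04-fold) and Fosl2 (6.997-fold) rose most. Nptx2 went from 36.8 ± 18.5 to 266 ± 23.1 (7.80-fold, log2 2.96, SE 0.35, adjusted p = 9.80e-04). Its level in Emx was far higher, and PV libraries held Slc17a7 at 1540, against 23451 in Emx. The rise of Nptx2 in PV therefore cannot be assigned to PV neurons alone. SST libraries changed in 58 genes (57 higher, 1 lower; 773 with the block, 577 higher). The top rises were Fosb (58.2-fold), Egr2 (14.4-fold), Cdkn1a (14.0-fold), Npas4 (14.0-fold), Egr3 (13.9-fold) and Nptx2 (13.8-fold). Npy2r, a neuropeptide Y receptor, was the 1 gene to fall (log2 -1.92, adjusted p = 0.0372). Within the VIP line 40 genes (40 higher, 0 lower; 311 with the block, 262 higher) changed, and Fosb (29.9-fold), Cdkn1a (11.7-fold), Ptgs2 (9.09-fold), Fosl2 (8.21-fold), Egr2 (7.84-fold) and Egr3 (6.59-fold) stood at the top. Ptgs2, an inducible prostaglandin synthase, rose from 43.2 ± 1.25 to 405 ± 63.8 (9.09-fold, log2 3.18, SE 0.28, adjusted p = 6.80e-06). Raised in all 5 lines were 4 genes, Egr3, Fosb, Fosl2 and Nptx2 (43 with the block), of 176 raised in any. Emx and SST shared 35 where 0.555 were due by chance (Fisher exact test, adjusted p = 8.72e-57).

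Of 16 activity-regulated secreted factors measured, 8, 1, 2, 3 and 6 rose at 3 h in Emx, Gad2, PV, SST and VIP (10, 10, 8, 7 and 11 adjusted over the list alone). The list was called in each line (adjusted p = 5.43e-05 to 0.00482 with an estimated correlation). Bdnf, a neurotrophin, rose 6.95-fold in Emx, 6.77-fold in PV, 4.74-fold in SST and 5.54-fold in VIP. In the VIP line the 6 members that rose were Bdnf (5.54-fold), Vgf (4.44-fold), Nptx2 (2.67-fold), Igf1 (2.05-fold), Pcsk1 (1.92-fold) and Pthlh (1.84-fold). Homer1, a postsynaptic scaffold gene of the effector list, rose 3.996-fold in Emx and 2.78-fold in VIP, and Kcna1, a potassium channel that shortens firing, rose 2.27-fold in VIP (adjusted p = 0.00182). Leaving out 1 library moved the counts to 70 to 128 (Emx), 9 to 14 (Gad2), 7 to 15 (PV), 33 to 47 (SST), 19 to 54 (VIP). Such omissions ended the calls of Timp1, Egr2 and the 4 named falls in Emx, Arc in Gad2, Egr2 in PV and VIP, and Npy2r in SST (largest adjusted p 0.306, Npy2r). SST markers (0.45) and VIP markers (0.45) had positive median log2 changes in the PV line at this time, called only with the preset correlation (adjusted p = 0.342 and 0.252 with an estimated correlation).

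At 7.5 h of light the number of genes called was at its highest in the Emx, Gad2, PV and SST lines. The Emx line changed 538 genes (356 higher, 182 lower; 3675 with the block, 1827 higher). Timp1, an inhibitor of matrix metalloproteinases, rose from 1.91 ± 1.73 to 206 ± 32.2 (78.7-fold, log2 6.30, SE 0.82, adjusted p = 5.60e-04) . Cdkn1a rose from 419 ± 59.9 to 5668 ± 1287 (13.4-fold, log2 3.74, SE 0.21, adjusted p = 4.36e-07), and Inhba (19.9-fold), Crct1 (15.9-fold), Egr2 (15.2-fold) and Sphk1 (13.3-fold) were next to it in size. Falls there were headed by Fcrlb (-2.97 in log2), Tusc5 (-2.72), Tap1 (-2.58) and Fam129a, which was listed at 0 in all 3 libraries at 7.5 h. Fcrlb (0.408 ± 0.706), Tusc5 (2.09 ± 2.09) and Tap1 (1.11 ± 1.05) also stood near 0 in Emx at 7.5 h. In those 3 libraries 1 read was worth 1.40, 1.22 and 2.09. The size of these falls thus depends on the pseudocount and the low depth. Gad2 libraries changed in 54 genes (49 higher, 5 lower; 1171 with the block, 763 higher), and Fosb (15.52-fold), Plin4 (13.3-fold), Fndc9 (12.2-fold), Egr2 (10.9-fold), Cdkn1a (10.3-fold) and Arc (9.18-fold) rose most. Fndc9 went from 38.8 ± 3.74 to 488 ± 79.2 (12.2-fold, log2 3.61, SE 0.19, adjusted p = 4.24e-07). Their largest falls were Slc45a2 (-1.93), Dbp (-1.20), Accs (-1.10) and Xrcc3 (-0.91) in log2. In the PV line 43 genes (42 higher, 1 lower; 1119 with the block, 749 higher) changed, led by Fos (19.5-fold), Fosb (13.7-fold), Nptx2 (12.7-fold), Cdkn1a (11.9-fold), Egr2 (10.7-fold) and Bdnf (9.04-fold). Bdnf rose from 25.2 ± 7.31 to 236 ± 60.0 (9.04-fold, log2 3.18, SE 0.35, adjusted p = 3.34e-04), and Xrcc3, a DNA repair gene, fell (log2 -0.94). SST libraries changed in 158 genes (139 higher, 19 lower; 2419 with the block, 1425 higher). Rising most were Fosl1 (54.2-fold), Fosb (52.1-fold), Egr2 (49.4-fold), Timp1 (40.3-fold), Nptx2 (27.0-fold) and Fndc9 (24.97-fold), and falling most Htra4 (-3.15), Npy2r (-2.13), Ccdc151 (-1.59) and Lsmem1 (-1.57) in log2. Nptx2 rose from 83.6 ± 7.14 to 2417 ± 1027 (27.0-fold, log2 4.76, SE 0.28, adjusted p = 2.98e-06). VIP libraries changed in 35 genes (33 higher, 2 lower; 226 with the block, 193 higher). Filip1l was listed at 0 in the dark libraries and stood at 48.5 ± 42.8 at 7.5 h, and Egr2 (15.6-fold), Inhba (13.3-fold), Ptgs2 (8.20-fold), Cdkn1a (7.96-fold) and Arc (7.86-fold) rose. The 2 falls were Dbp, a transcription factor driven by the circadian clock, from 625 ± 234 to 169 ± 51.6 (log2 fold change -1.84, adjusted p = 0.0186), and Sytl2, from 693 ± 20.8 to 314 ± 19.2 (log2 fold change -1.14, adjusted p = 0.0184). Crct1 in Emx (0.570 ± 0.987), Plin4 in Gad2 (0.328 ± 0.292) and Fosl1 in SST (0.732 ± 1.04) lay below 1 in the dark, so the pseudocount sets the size of their folds. With 0.1 in its place their log2 changes came out larger, and the calls of Plin4 and of Timp1 in SST were lost.

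Raised in all 5 lines at 7.5 h were 11 genes, Arc, Bdnf, Cdkn1a, Egr1, Egr2, Egr3, Etv5, Fos, Fosb, Fosl2 and Stk40 (107 with the block, which include all of these but Fos), out of 420 raised in any line. Emx and SST shared 84 rises where 3.47 were due by chance, and Gad2 and PV 26 where 0.145 were due (Fisher exact test, adjusted p = 2.76e-99 and 2.35e-56). The Gad2 line marks inhibitory neurons in general, PV neurons included, so that overlap is not one of separate classes. The secreted factors that rose numbered 9, 5, 3, 7 and 6 of 16 in Emx, Gad2, PV, SST and VIP (12, 11, 10, 9 and 12 adjusted over the list alone; adjusted p = 5.43e-05 to 0.00212 for the list with an estimated correlation). Examples are Scg2, a granule protein, in Emx (3.08-fold), Vgf, a precursor of secreted peptides, in SST (6.21-fold) and VIP (4.28-fold), and Cbln4, a synaptic organizer, in Gad2 (3.19-fold). These 3 genes were chosen after their values were seen, the largest rises of the list being those of Inhba, Nptx2 and Bdnf. Of the immediate early factors, 11, 9, 10, 14 and 9 of 20 were raised in Emx, Gad2, PV, SST and VIP. Leaving out 1 library moved the counts to 234 to 440 (Emx), 27 to 42 (Gad2), 25 to 39 (PV), 58 to 118 (SST), 14 to 38 (VIP). Calls ended for all 4 named falls in Emx, for Plin4, Slc45a2, Dbp and Accs in Gad2, Xrcc3 in PV, Fosl1, Timp1 and the 4 falls in SST, and Filip1l, Inhba, Dbp and Sytl2 in VIP (largest adjusted p 0.405, Ccdc151 in SST).

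Compared with dark housing, standard housing raised early factors in the Emx, Gad2, PV and VIP lines. Emx libraries differed in 15 genes (15 higher, 0 lower; 133 with the block, 109 higher), led by Egr2 (17.7-fold), Fos (8.30-fold), Arc (5.90-fold), Npas4 (5.08-fold), Fosb (4.82-fold) and Nr4a1 (4.68-fold). The Gad2 line differed in 6 genes (6 higher, 0 lower; 120 with the block, 101 higher), namely Fos (9.12-fold), Fosb (8.37-fold), Npas4 (6.69-fold), Egr1 (4.45-fold), Fosl2 (3.38-fold) and Cdkn1a (2.89-fold). PV libraries differed in 12 genes (11 higher, 1 lower; 347 with the block, 237 higher), among them Fos (12.04-fold), Egr2 (8.501-fold), Egr1 (5.61-fold), Bdnf (4.28-fold), Nr4a1 (4.22-fold) and Arc (4.16-fold). Best3, a chloride channel gene, was listed at 0 in all 3 standard libraries against 11.8 ± 6.15 in the dark. With 2 libraries against 2, limma called 0 genes in the SST line, 49 with the block and 0 with voom. Its unadjusted p was under 0.05 for 275 of 14205 genes, fewer than the share of 0.05 due by chance. Such a low share also occurred in contrasts with calls, as in VIP at 1 h (275 of 14181, 41 called) and PV at 1 h (217 of 14189, 22 called). It is thus no sign that standard housing changed nothing in the SST line. VIP libraries differed in 17 genes (17 higher, 0 lower; 51 with the block, 50 higher): Filip1l (0 in the dark, 35.4 ± 14.2 in standard housing), Fosb (19.9-fold), Egr2 (14.9-fold), Fos (13.7-fold), Npas4 (10.7-fold) and Nr4a1 (8.18-fold). No gene was higher in all 5 lines, and Emx and VIP shared 10 where 0.0180 were due by chance (Fisher exact test, adjusted p = 1.20e-27). The immediate early list was called in each line, with 8, 5, 6, 0 and 10 of 20 members higher (18, 15, 12, 2 and 16 adjusted over the list alone; adjusted p = 2.99e-04 to 0.0451 with an estimated correlation). With the block, the calls of Arc in Emx (adjusted p = 0.0596) and Npas4 in VIP (0.181) were lost. Left-out libraries moved the counts to 5 to 35 (Emx), 2 to 6 (Gad2), 2 to 6 (PV), 10 to 16 (VIP). Here every named gene lost its call without at least 1 library except Fos in Emx, Gad2, PV and VIP, Fosb in Gad2 and VIP, Egr1 in PV, and Egr2 and Nr4a1 in VIP. Standard libraries were sequenced to a lower depth than dark ones.

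Igf1, which encodes insulin-like growth factor 1, was by far most abundant in the VIP line and rose there with light. Over all conditions it stood at 20665 ± 5946 in the VIP line (n = 15), 3344 ± 585 in Gad2 (n = 15), 2765 ± 551 in SST (n = 13), 206 ± 70.7 in PV (n = 15) and 45.7 ± 20.9 in Emx (n = 15). VIP exceeded the mean of PV and SST by 4.76 in log2 (SE 0.10, adjusted p = 5.06e-42). In the VIP line the dark level of 13007 ± 1217 went to 16427 ± 2656 at 1 h (log2 0.33, adjusted p = 1). It rose to 26665 ± 1194 at 3 h (2.05-fold, log2 1.04, SE 0.15, adjusted p = 0.00283, 3.86e-07 with the block) and to 26557 ± 3400.4 at 7.5 h (2.04-fold, adjusted p = 0.00364, 4.85e-07 with the block). All 3 libraries at each of these times lay above all 3 dark libraries. In standard housing the level was 20667 ± 2227 (log2 0.67, adjusted p = 0.173, 4.46e-04 with the block). No other line passed the test without the block. Gad2 went from 2644 ± 277 to 4005 ± 425 at 3 h (log2 0.60, adjusted p = 0.191, 6.26e-07 with the block). SST went from 2484 ± 227 to 3339.6 ± 683 at 7.5 h (log2 0.41, 0.497 and 1.58e-04), and Emx from 22.6 ± 4.89 to 63.5 ± 24.4 at 7.5 h (log2 1.41, 0.0829 and 0.00366). PV went from 155 ± 30.4 to 258 ± 73.2 (log2 0.70, 0.772 and 0.0545). The VIP response exceeded the mean of PV and SST by 0.31, 0.82 and 0.47 in log2 at 1 h, 3 h and 7.5 h (SE 0.33), which the test of the difference did not separate from 0 (adjusted p = 0.893, 0.243 with the block).

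**Figure D2:**
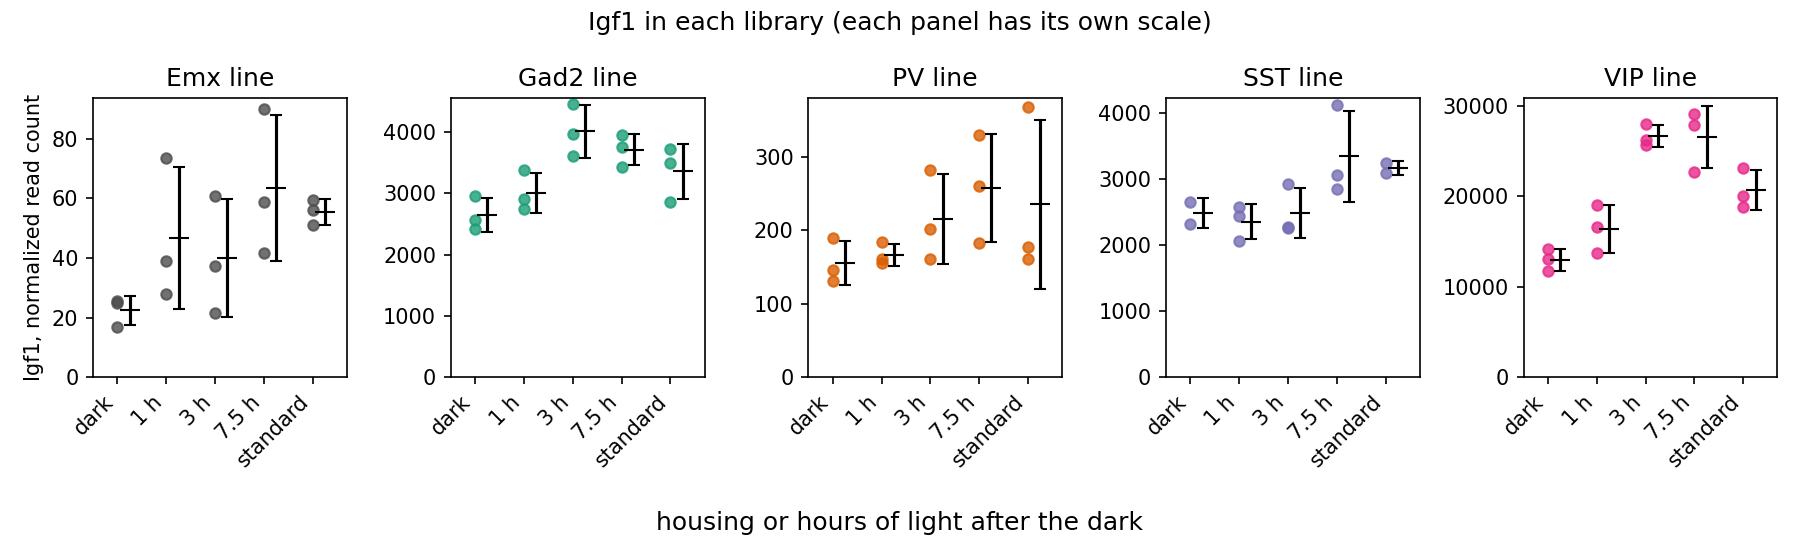
Normalized read counts of Igf1 in each library (points) with the group mean and SD (bars), by condition, in the 5 Cre lines, each panel on a scale of its own. VIP libraries averaged 13007 in the dark, 26665 at 3 h and 26557 at 7.5 h, Emx libraries 22.6 in the dark and 63.5 at 7.5 h.

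The list of 15 genes of IGF and insulin signalling was called in 0 of 20 contrasts with limma camera, at the preset or an estimated correlation, and in 1 with the block (SST in standard housing, downward, median -0.11, adjusted p = 0.0175, and 0.223 with an estimated correlation). Members that rose besides Igf1 were Irs2, an adaptor of the insulin and IGF receptors, in Emx at 1 h (3.46-fold), 3 h and 7.5 h and in SST at 3 h and 7.5 h (3.33-fold).

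The test of levels between lines covered 14206 genes. The PV line differed from SST and VIP in 2665 genes (876 higher, 1789 lower; 2625 with the block). Pdlim3 was 112-fold higher (1720.1 ± 504 in PV, 12.7 in SST, 26.5 in VIP) and Pvalb 27.6-fold higher. Calb2 (calretinin) was 161-fold lower, Tac2 127-fold, Grpr 116-fold, Slc5a7 94.3-fold and Ppapdc1a 91.2-fold lower. The SST line differed from PV and VIP in 1263 genes (732 higher, 531 lower; 1288 with the block). Pdyn, the dynorphin precursor, was 205-fold higher, Chodl 112-fold, Chrna2 101-fold, Myh13 92.6-fold, Hpse 89.5-fold and Sst itself 88.5-fold. The VIP line differed from PV and SST in 2768 genes (1810 higher, 958 lower; 2883 with the block). Beside Vip (771-fold) these included the cholinergic genes Slc18a3 (708-fold) and Chat (503-fold), the serotonin receptor Htr3a (578-fold), Tac2 (569-fold) and Rspo4 (408-fold). Emx differed from Gad2 in 3608 genes (2148 higher, 1460 lower; 3578 with the block). Akr1c18 was 273-fold lower, Crhbp 248-fold, Gad1 233-fold, Npy 214-fold, Pnoc 197-fold and Sst 188-fold lower, Slc17a7 21.3-fold higher and Emx1 14.2-fold higher. Chodl (0.494), Chrna2 (0.473), Slc18a3 (0.734), Chat (0.286) and Rspo4 (0.200) lay below 1 in the PV line, and Rspo4 (0.568) also in SST, so the pseudocount sets the size of their folds. The genes with the largest differences had adjusted p-values of 5.18e-25 or less.

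Some light responses differed between lines by a test of the difference itself. The SST line differed from PV and VIP in 16 genes, 15 of them also called with a spread for each line, a setting that called 32 in all (126 with the block). Tpbg, a membrane glycoprotein of Wnt signalling, rose in SST from 144 ± 3.71 to 2534 ± 1024 (16.6-fold, log2 4.06, SE 0.26, adjusted p = 2.98e-06) at 7.5 h. Its log2 change was 1.73 in PV (adjusted p = 0.00334) and -0.04 in VIP, where the dark level was already 2163 ± 455. Unc5b, a netrin receptor, rose in SST from 56.2 ± 10.2 to 429 ± 33.7 (7.56-fold, log2 2.92, SE 0.30, adjusted p = 2.33e-04) and had log2 0.44 in PV and 0.06 in VIP, neither called. Nptx2 responded more in SST than in PV and VIP by 2.29 in log2 at 7.5 h (adjusted p = 0.00279). The PV line differed in 3 genes (all 3 among the 7 called with a spread for each line; 91 with the block), each with a negative difference. This count is not firm, since it depended on the setting. On simulated data 4 unchanged genes were called for PV, but beside 82.1% of 95 genes with a 4-fold difference. Those 4 are therefore no measure of the 3 called here. Gadd45b, a stress and activity gene, stood 1.82-fold higher in PV at 1 h against 8.82-fold in SST and 4.28-fold in VIP (log2 difference -1.76, adjusted p = 0.0235). The others were Nefm, a neurofilament, and Srxn1, an antioxidant enzyme, which rose 4.32-fold in VIP at 3 h (adjusted p = 2.19e-06). The VIP line differed from PV and SST in 50 genes, 18 of them among the 25 called with a spread for each line (758 with the block). On the simulated data 35 unchanged genes were called for VIP, so the count of 50 is not firm either. Emx differed from Gad2 in 22 genes, all 22 among the 102 called with a spread for each line (308 with the block). Blocked counts of differing responses are overstated on simulated data. Rnd3 rose in Emx from 396 ± 75.5 to 1655 ± 360.1 (4.16-fold, log2 2.06, SE 0.20, adjusted p = 5.76e-05) and had log2 0.18 in Gad2 (difference 2.05 at 3 h, adjusted p = 3.05e-10). Ptgs2 rose 9.94-fold in Emx at 3 h against 1.53-fold, not called, in Gad2.

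**Figure D3:**
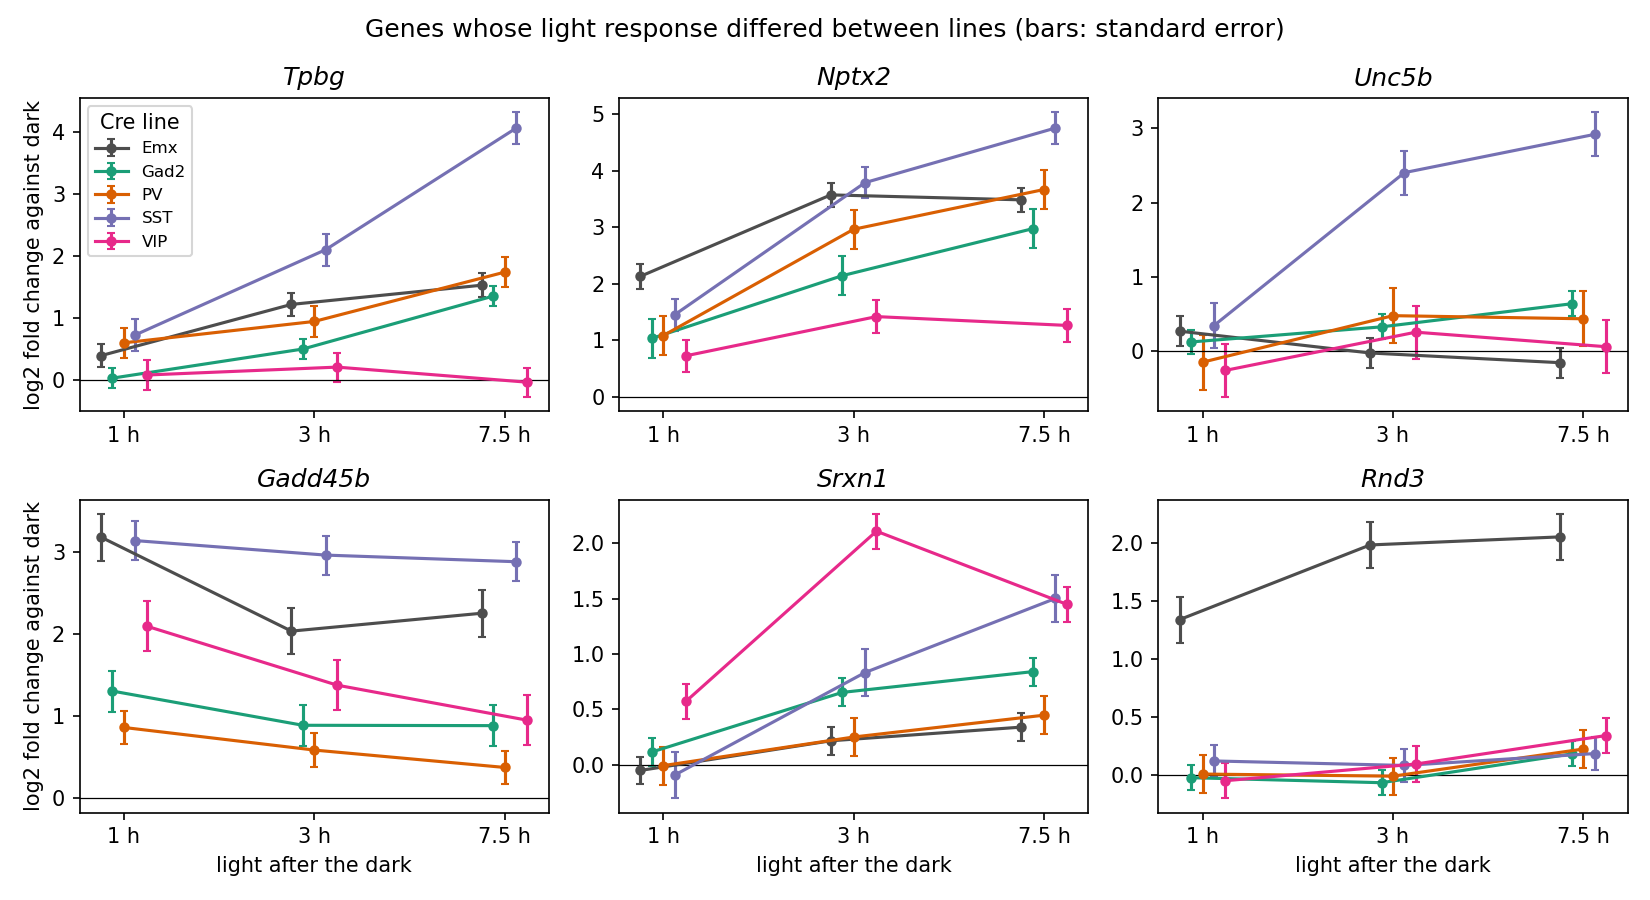
Log2 fold change against dark housing (points, with the SE as bars) at 1 h, 3 h and 7.5 h of light for genes whose light response differed between Cre lines, 1 panel per gene. Tpbg reaches 4.06 at 7.5 h in SST against -0.04 in VIP, and Rnd3 2.06 in Emx against 0.18 in Gad2.

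Several genes of the circadian clock changed with light. At 1 h the 17-gene list was called upward in all 5 lines with the preset correlation (adjusted p = 0.195 in Emx and 0.00348 to 0.00632 in the others with an estimated correlation), though its median was below 0.2 in log2 in each. It had 2, 0, 1, 3 and 2 members rising in Emx, Gad2, PV, SST and VIP (5, 4, 3, 5 and 3 adjusted over the list alone). Per1, a repressor of the clock that light induces, rose from 1641 ± 298 to 7357 ± 1679 (4.45-fold, log2 2.15, SE 0.32, adjusted p = 0.00261) in VIP and 3.76-fold in SST. Nfil3 rose in Emx (3.52-fold), PV, SST and VIP. At 7.5 h Dbp fell in Emx (log2 -1.64, adjusted p = 6.40e-04), Gad2 (-1.20, 0.00921) and VIP (-1.84, 0.0186). Its log2 change was -0.94 in PV (adjusted p = 0.103, 7.71e-06 with the block) and -0.93 in SST (0.410, 1.33e-04 with the block). In Emx, 3 members rose and 3 fell at that time (6 and 7 adjusted over the list alone), and the list as a whole was not called there.

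**Figure D4:**
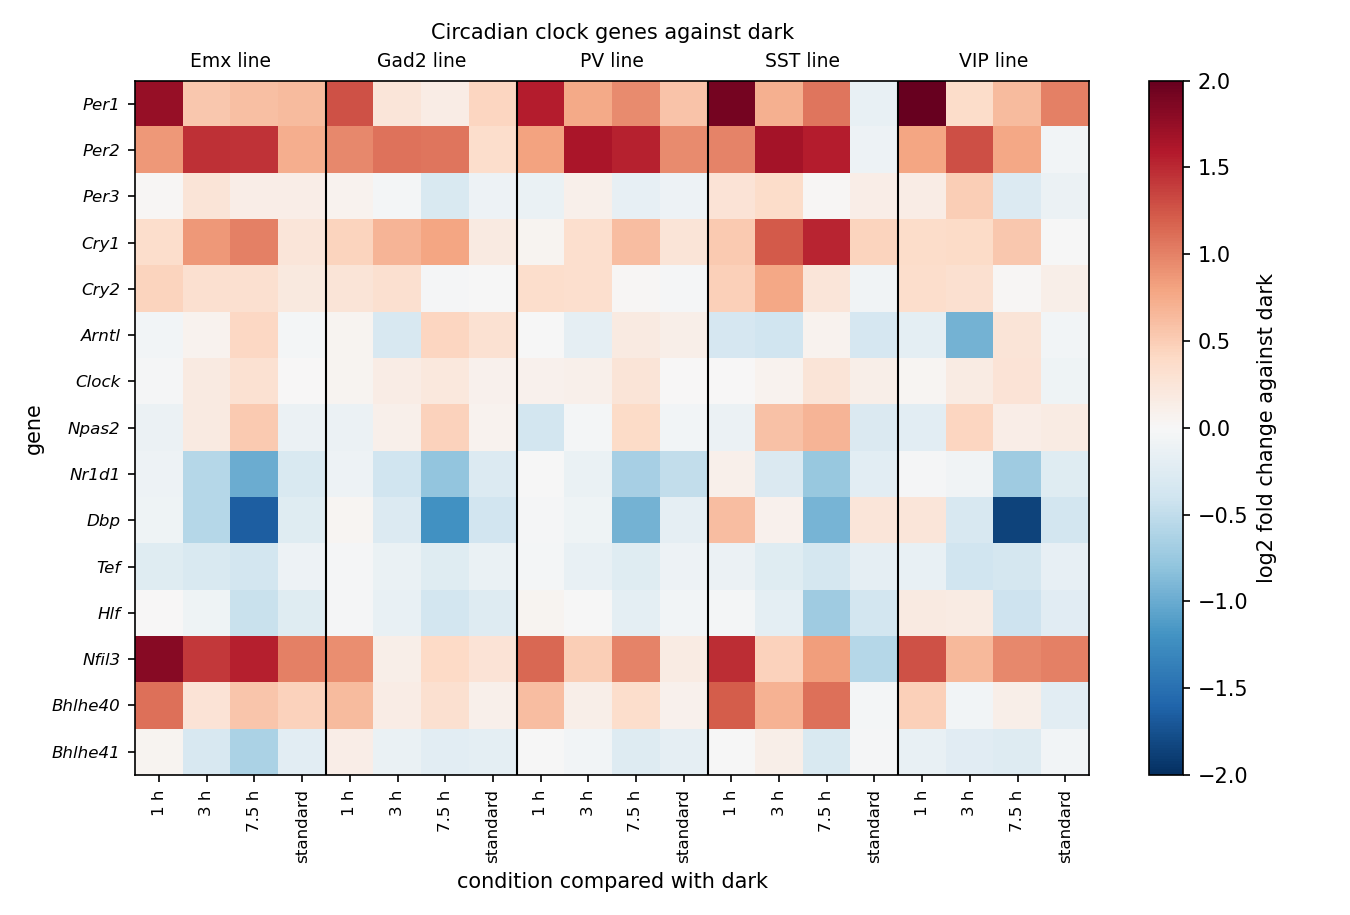
Log2 fold change against dark housing (colour) of clock genes, by Cre line and by 1 h, 3 h and 7.5 h of light and standard housing. Dbp at 7.5 h lies between -1.84 in VIP and -0.93 in SST, and Per1 at 1 h between 1.28 in Gad2 and 2.15 in VIP.

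Heat shock and unfolded protein response genes were called upward in 19 of 20 contrasts with the preset correlation, all but SST in standard housing, and in 15 with an estimated one. At 7.5 h the median log2 change of the 16 genes was 0.63, 0.39, 0.34, 0.50 and 0.55 in Emx, Gad2, PV, SST and VIP (adjusted p = 0.00180 to 0.0300 with an estimated correlation). In number, 7, 2, 1, 1 and 1 members rose (9, 8, 4, 7 and 7 adjusted over the list alone). Dnajb5, a co-chaperone, rose 3.54-fold in Emx and 3.33-fold in SST, and Hspa5, the chaperone of the endoplasmic reticulum, 1.73-fold in PV.

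Over all 14 lists and 20 contrasts, 131 of 280 tests were called with the preset correlation and 84 with an estimated one. The immediate early and secreted lists were called in 20 of 20 either way, and the effectors in 20 and 19, losing SST in standard housing (adjusted p = 0.105 with an estimated correlation). The clock went from 7 to 5. Neuropeptides were called upward in 16 of 20 contrasts with the preset correlation but in 2 with an estimated one. These were PV at 3 h (median 0.63, adjusted p = 0.0244 with an estimated correlation) and at 7.5 h (0.51, 0.0300). In the same line SST and VIP neuron markers moved alongside, with medians of 0.45 and 0.45 at 3 h and 0.44 and 0.55 at 7.5 h, and 6 of the 15 neuropeptides (Sst, Pdyn, Vip, Crh, Cck and Penk) belong to those marker lists, so RNA of other classes is not ruled out. Crh, corticotropin-releasing hormone, rose 7.11-fold in Emx at 3 h, and Vip 11.01-fold in Emx and 6.31-fold in SST at 7.5 h, lines other than its own. VIP neuron markers had positive medians in Emx at these times too, but were not called with an estimated correlation. Crh and Vip are themselves on that list, so its medians are no separate evidence on where their RNA came from. Excitatory synapse genes were called in 5 contrasts, inhibitory synapse genes in 4, perineuronal net and matrix genes in 3 and voltage-gated potassium channels in 10. Each was called in 0 with an estimated correlation (smallest adjusted p = 0.470, 0.0768, 0.0964 and 0.127 with an estimated correlation). In the matrix list Timp1 rose in Emx and SST, Acan (aggrecan) 7.56-fold in Emx, and Mmp9 fell in SST at 7.5 h (log2 -0.95, adjusted p = 0.00421). Cholesterol synthesis was called in 7 contrasts, 3 of them with an estimated correlation: Emx at 1 h (median 0.13, adjusted p = 0.00740), Emx in standard housing (median 0.18, adjusted p = 0.00484) and SST in standard housing (0.40, 0.00209). Oxidative phosphorylation and cytosolic ribosomal proteins were each called in 0 contrasts with limma camera, with the block in 7 and 13, and in 0 with the block and an estimated correlation.

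Markers of other cell types moved with some conditions. VIP neuron markers were higher in the Emx line in standard housing (median 1.12, adjusted p = 2.59e-09, and 0.00804 with an estimated correlation), the 1 call of 200 marker tests that held with an estimated correlation out of 14 with the preset one. At 7.5 h their median in Emx was 0.61 and at 3 h 0.77 (adjusted p = 0.0951 and 0.171 with an estimated correlation). Microglia markers were lower in the Gad2 line at 1 h (median -0.78) and 3 h (-1.18; adjusted p = 0.342 and 0.268 with an estimated correlation), with 9 of 10 lower at 3 h when adjusted over the list alone. The other calls were lost with an estimated correlation: inhibitory markers in Emx at 1 h and 3 h (adjusted p = 0.478 and 0.342) and oligodendrocyte markers in Emx at 1 h (0.478). So were excitatory (downward, 0.732) and PV markers (0.268) in Gad2 in standard housing, VIP markers in PV at 7.5 h (0.268) and endothelial markers in SST in standard housing (downward, 0.268). Astrocyte and oligodendrocyte precursor markers were called in 0 of 20 contrasts each.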

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

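Of the tests in this part, the spread fitted for each line, voom and the draws within replicate numbers were chosen only after the result was seen, and the 100 draws over whole lines were fixed before. A light response was singled out where the test of the difference between lines itself passed. Differences are in log2 at the time where they were largest.

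In the SST line against PV and VIP, 16 genes differed: Tpbg (3.21 at 7.5 h, adjusted p = 4.69e-12), Unc5b (2.67 at 7.5 h, adjusted p = 3.17e-05), Nptx2 (2.29 at 7.5 h, adjusted p = 0.00279), Gadd45b (2.22 at 7.5 h, adjusted p = 6.21e-04), Fstl4 (1.74 at 7.5 h, adjusted p = 0.00449) and Filip1l (-2.03 at 7.5 h, adjusted p = 0.00893) were the 6 with the largest difference. The negative value of Filip1l arises because that gene went up in the VIP line, not down in SST (log2 0.45 at 7.5 h). In 2 of 100 draws that dealt the conditions anew within each line, the real one included, as many genes were called. The highest other draw called 144, several times the real count, which points to a structure of the samples, and these draws do not keep libraries of one replicate number together. Draws that dealt the conditions only among libraries of one line and replicate number called as many in 2 of 100 (highest other 17). Both kinds of draw also take away the light response that the lines share and add it to the spread. They therefore cannot exclude chance for a response that differs between lines. In the PV line 3 genes differed: Gadd45b (-1.76 at 1 h, adjusted p = 0.0235), Nefm (-1.47 at 7.5 h, adjusted p = 0.0488) and Srxn1 (-1.22 at 3 h, adjusted p = 6.46e-05). Here 7 of 100 draws over whole lines called as many (highest other 486), and 2 of 100 within replicate numbers (highest other 3). For the reason given, neither kind of draw excludes chance for the count. The count became 7 with a spread for each line, so it is not firm. Emx differed from Gad2 in 22 genes, with Rxfp3 (3.80 at 7.5 h, adjusted p = 0.0330), Sphk1 (3.61 at 7.5 h, adjusted p = 0.0343), Ptgs2 (2.70 at 3 h, adjusted p = 2.38e-04), Rnd3 (2.05 at 3 h, adjusted p = 3.05e-10), Gm13889 (1.88 at 1 h, adjusted p = 0.0206) and Gadd45b (1.87 at 1 h, adjusted p = 0.0396) the 6 furthest apart. Rxfp3 stood at 0.539 ± 0.493 in the dark Emx libraries, below the pseudocount of 1, which therefore sets the size of its difference. Only 1 of 100 draws of either kind, the real one, called as many (highest other 4 over whole lines and 18 within replicate numbers). For the reason given, this does not exclude chance for a differing response.

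The VIP line differed from PV and SST in 50 genes, with Filip1l (5.24 at 7.5 h, adjusted p = 6.55e-10), Tmem140 (4.33 at 3 h, adjusted p = 0.0477), Slc1a7 (4.12 at 7.5 h, adjusted p = 0.0219), 3110062M04Rik (-3.98 at 3 h, adjusted p = 2.65e-04), Dpt (-3.67 at 7.5 h, adjusted p = 0.00375) and Fkbp11 (-3.56 at 3 h, adjusted p = 0.0198) furthest apart. As many were called in 10 of 100 draws over whole lines (highest other 1049), where draws that call several times the real number point to a structure of the samples, and in 1 of 100 within replicate numbers, the real one (highest other 38). Neither kind of draw excludes chance for the count, since both take away the light response that the lines share. With 35 unchanged genes called on simulated data, the count is not firm. With a spread for each line, Tmem140 (adjusted p = 0.949), Slc1a7 (0.120) and Fkbp11 (0.164) were no longer called. Most of these 6 genes rest on libraries listed at or near 0. Filip1l was at 0 in the 3 dark VIP libraries, Dpt at 0 in the 3 VIP libraries at 7.5 h, and 3110062M04Rik stood at 7.96 ± 13.8 in VIP at 3 h against 43.9 ± 12.6 in the dark, so the size of these differences depends on the pseudocount. Tmem140 and Slc1a7 also lost their calls with a pseudocount of 0.1 (0.396 and 0.505), Slc1a7 and Fkbp11 with voom (0.174 and 0.0828) and Tmem140 with the block (0.0570), whereas Filip1l, 3110062M04Rik and Dpt passed with each of these. No biological explanation was tested for these genes.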

How the results depend on the processing

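Among the alternatives here, voom, the filter of at least 50, keeping the genes at 0, the spread for each line and the block combined with an estimated correlation are tests chosen only after the result was seen. The Igf1 rise in the VIP line kept its direction and its call at 3 h and 7.5 h under each alternative, those leaving out 1 library included (largest adjusted p 0.0354 and 0.0382). Of the 28 counts of genes, rescaling moved 0 by more than 1.5 times, no filter 1, the filter of at least 50 1, the pseudocount 2, keeping the genes at 0 2, voom 6, the pooled spread 8 of 20, the spread for each line 4 of 8 and the block 24. Leaving out 1 library moved 85 of 436. Among named genes, calls were lost in 8 of 562 with the block, 61 with voom, 11 with the pseudocount, 6 of 541 with the filter of at least 50, 4 of 562 with rescaling, 3 with no filter, 1 with the genes at 0 kept, 38 of 488 with the pooled spread, 3 of 74 with the spread for each line, and 951 on leaving out 1 library (4867 kept), so a call of a single gene often needed all libraries. Depth limits low genes, and the variation between replicates limits abundant ones. Where leaving out 1 library leaves SST dark or standard with 1, that library is assumed to vary like the other groups. The cause of each change below was not tested, unless stated.

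With the replicate block, counts at 1 h, 3 h, 7.5 h and in standard housing became 404, 1739, 3675 and 133 in Emx, 181, 442, 1171 and 120 in Gad2, 77, 140, 1119 and 347 in PV, 194, 773, 2419 and 49 in SST, 84, 311, 226 and 51 in VIP. By its construction the block takes out the variation between replicate numbers. Igf1 then passed in Emx at 7.5 h (1.41 in log2), Gad2 at 3 h (0.60), 7.5 h (0.49) and in standard housing (0.34), SST at 7.5 h (0.50) and VIP in standard housing (0.67). Its change in SST turned from -0.080 to 0.0068 at 1 h and from -0.0079 to 0.079 at 3 h, none of them called (largest adjusted p 0.992), and the level of Emx1 in SST against PV and VIP from -0.20 to 0.0055. In SST the group means rest on different replicate numbers, which the block weighs anew. Differing responses became 91 (PV), 126 (SST), 758 (VIP) and 308 (Emx against Gad2), and calls of lists 1 for IGF and insulin signalling, 7 for oxidative phosphorylation and 13 for ribosomal proteins.

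With the spread pooled over all lines, counts became 31 in Emx in standard housing, 30, 132 and 51 in PV at 3 h, 7.5 h and in standard housing, and 93, 449, 298 and 117 in VIP, and Igf1 passed in Emx at 7.5 h (1.41) and in standard housing (1.28). The count of Gad2 in standard housing became 3 with a pseudocount of 0.1, 3 with no filter, 3 with voom, 3 with the filter of at least 50 and 11 with the genes at 0 kept. Voom gave 6 in PV in standard housing and 22 in VIP at 7.5 h. Differing responses of PV became 7 with the pseudocount of 0.1, 7 with voom, 7 with the genes at 0 kept and 7 with the spread for each line, which gave 32 in SST, 25 in VIP and 102 in Emx against Gad2. With voom VIP had 76 and Emx against Gad2 38. Rescaling by median ratios turned the uncalled change of Igf1 in SST at 3 h to 0.0071. With an estimated correlation, calls of lists became 2 (neuropeptides), 0 (excitatory synapse), 0 (inhibitory synapse), 0 (perineuronal net and matrix), 0 (potassium channels) and 3 (cholesterol synthesis), and with the block as well 8, 2, 1, 0, 2 and 2, 3 for the clock and 9 for heat shock.

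Leaving out 1 library at a time gave these ranges, followed by each library (group and replicate number) that moved a count by more than 1.5 times, with the count without it. In Emx the count ran over 1 h 49 to 81, with 58 (dark 3), 49 (1 h 2), then over 3 h 70 to 128, with 75 (dark 2), 70 (dark 3), 73 (3 h 2), 92 (3 h 3), then over 7.5 h 234 to 440, with 352 (dark 1), 254 (dark 2), 234 (dark 3), 255 (7.5 h 1), then over standard 5 to 35, with 5 (dark 2), 5 (dark 3), 35 (standard 1), 5 (standard 2), 5 (standard 3). In Gad2 the count ran over 1 h 16 to 26, with 16 (dark 3), 20 (1 h 1), 17 (1 h 2), 20 (1 h 3), then over 3 h 9 to 14, with 11 (dark 2), 10 (dark 3), 9 (3 h 1), 9 (3 h 3), then over 7.5 h 27 to 42, with 33 (dark 1), 33 (dark 2), 33 (dark 3), 27 (7.5 h 1), then over standard 2 to 6, with 2 (dark 1), 3 (dark 2), 2 (dark 3), 2 (standard 1), 3 (standard 2). In PV the count ran over 3 h 7 to 15, with 7 (dark 3), 7 (3 h 1), then over 7.5 h 25 to 39, with 25 (dark 3), 25 (7.5 h 1), 26 (7.5 h 3), then over standard 2 to 6, with 6 (dark 1), 3 (dark 2), 4 (dark 3), 2 (standard 1), 2 (standard 2), 3 (standard 3). In SST the count ran over 1 h 25 to 36, with 28 (dark 1), 26 (dark 3), 25 (1 h 2), then over 3 h 33 to 47, with 36 (dark 1), 34 (dark 3), 38 (3 h 1), 33 (3 h 2), then over 7.5 h 58 to 118, with 58 (dark 1), 59 (dark 3), 97 (7.5 h 2), 92 (7.5 h 3). In VIP the count ran over 1 h 20 to 45, with 24 (dark 2), 23 (dark 3), 20 (1 h 2), then over 3 h 19 to 54, with 22 (dark 2), 19 (dark 3), 23 (3 h 1), 21 (3 h 2), then over 7.5 h 14 to 38, with 17 (dark 2), 14 (dark 3), 14 (7.5 h 1), 19 (7.5 h 2), 18 (7.5 h 3), then over standard 10 to 16, with 11 (dark 2), 10 (dark 3), 10 (standard 1). Leaving out VIP standard replicate 3, the library that stands apart, gave the highest counts of VIP at 1 h, 3 h and 7.5 h (45, 54, 38), since its spread enters the fit of the whole line.

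Differing responses ran over 1 to 9 in PV, with 1 (PV dark 1), 1 (PV dark 2), 9 (PV dark 3), 1 (PV 1 h 1), 6 (PV 3 h 2), 1 (SST dark 3), 1 (VIP dark 3), 5 (VIP 3 h 2), 6 (VIP standard 3), over 34 to 113 in VIP, with 113 (VIP 3 h 2), and over 10 to 25 in Emx against Gad2, with 14 (Emx dark 2), 14 (Emx dark 3), 13 (Emx 7.5 h 1), 14 (Gad2 dark 1), 13 (Gad2 dark 2), 10 (Gad2 7.5 h 3). Values near 0 that were not called changed sign: Igf1 in SST at 1 h (-0.17 to 0.01; 0.013 (SST dark 1), 0.014 (SST 1 h 2)) and at 3 h (-0.13 to 0.09; 0.086 (SST dark 1), 0.051 (SST 3 h 2), 0.056 (SST 3 h 3)), the difference in the light response of Igf1 in PV (-0.28 to 0.12; 0.081 (PV dark 1), 0.117 (PV 3 h 3)) and the level of Pvalb in SST against PV and VIP (-0.23 to 0.07; 0.023 (SST dark 1), 0.066 (SST standard 1)).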

Other observations

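Of the tests in this part, those of VIP neuron RNA and of microglia RNA for the rise of Igf1, of inhibitory RNA for Vip in Emx, and both tests of Dbp were chosen only after the result was seen. Igf1 rose 2.05-fold at 3 h in the VIP line. More VIP neuron RNA in the light libraries would raise the other genes of that class alike, but the median log2 change of 77 other genes at least 8-fold higher in the VIP line was 0.0638 at 3 h (SD 0.32) and 0.11 at 7.5 h (SD 0.28), against 1.04 and 1.03 for Igf1. RNA of microglia, which also express Igf1, is argued against by 10 of their markers (median 0.0627, SD 0.49, at 3 h and -0.16, SD 0.26, at 7.5 h), and scaling factors by the change after rescaling (1.04 at 3 h, adjusted p = 0.00284, and 1.02 at 7.5 h). A response of VIP neurons to light may thus underlie the rise, as a hypothesis found and tested on the same data. Whether it exceeds that of the PV and SST lines stays open (adjusted p of the difference 0.893).

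In the Emx line, Vip stood at 14.5, 20.8 and 28.2 in the 3 dark libraries, 129.8, 192 and 521 at 7.5 h (log2 3.46, adjusted p = 0.00546) and 112, 238 and 429 in standard housing (10.6-fold, adjusted p = 0.0511, and 2.82e-08 with the block), and Igf1 was higher at both (log2 1.41 and 1.28), not passing the test (adjusted p = 0.0829 and 0.883) but passing at 7.5 h with the block (0.00366, and 0.0728 in standard housing) and at both with the spread pooled over all lines. A larger share of all inhibitory neurons is argued against by their 10 markers, whose median was 0.49 at 7.5 h (SD 0.36) and 0.28 in standard housing (SD 0.29). RNA of VIP neurons carried into these libraries could be the source. As a share of its VIP line level, Vip gained 0.276% and Igf1 0.154% at 7.5 h. For 11 other abundant genes of that line the median was 0.127% (median absolute deviation 0.0423%, range -0.0469 to 0.383%). In standard housing the values were 0.267, 0.159 and 0.104% (deviation 0.0277%, range 0.0294 to 0.372%). Among the 11, Gad1, Gad2, Slc32a1 and Dlx1 mark inhibitory neurons in general. Gad2 held the highest share at 7.5 h, and Calb2, a VIP neuron marker, in standard housing. The median of the 11 thus does not measure VIP neuron RNA alone. In standard housing this median lay below 0.5 of the share of Vip by just more than its deviation, which was the bound set beforehand against carried-over RNA, but that bound was wrong in leaving out the spread of Vip itself, whose shares in the 3 libraries were 0.102, 0.243 and 0.456% against medians of 0.110, 0.0923 and 0.0846%. Since Vip lay below the median in the first of these libraries and the bound was not met at 7.5 h, carried-over RNA and a response of the cells of the Emx line cannot be told apart for either gene, nor is this settled by Vip being higher at 7.5 h and in standard housing in SST (6.31-fold and 5.99-fold, adjusted p = 0.0223 and 1, 5.22e-08 and 1.91e-05 with the block) and PV (2.33-fold and 2.07-fold, 0.507 and 1, 0.00553 and 0.0372), which either would allow. Libraries of these 2 conditions also shared a low depth (means of 14.6 and 16.2 M gene reads, against 33.2 M in the dark). What set their depth apart is thus confounded with light and housing here.

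Dbp had a log2 change of -1.84 to -0.93 over the 5 lines at 7.5 h, against -0.08 to 0.62 at 1 h, -0.57 to 0.09 at 3 h and -0.39 to 0.24 in standard housing. Libraries at 7.5 h and in standard housing shared a low depth (14.6 and 16.2 M reads), yet in 5 of 5 lines the fall in standard housing was under 0.5 of that at 7.5 h, which argues against library depth. For a moved phase of the clock, 30 of 30 changes at 7.5 h (Nr1d1, Tef and Hlf lower, Arntl, Clock and Npas2 higher, in each of 5 lines) went the way it needs, of which 1 was called and 21 with the block. These 6 genes were picked after their values were seen, leaving out Per1, Per2, Per3, Cry1, Bhlhe41 and Ciart, so this count decides nothing. A moved phase and an effect of light itself cannot be told apart, since the labels give no collection time.

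For the 16 contrasts of 3 against 3 libraries, the 10 splits of the 6 libraries are too few for a share under 0.05. The real split, 1 of 10, called 6 to 538 genes, and the highest other split called 1 in Emx at 7.5 h, 1 in PV at 3 h and 0 in the remaining contrasts. Since replicate numbers pair the libraries, the real split is set against the 3 others that part all 3 pairs. These called 0 genes without the block in each contrast, and with it at most 20 (Emx in standard housing, real 133), 1 (VIP at 7.5 h, real 226) and 0 elsewhere. Between lines, 1 of 100 draws called as many genes as the real assignment in each of the 4 comparisons, the real one itself. These draws dealt the lines anew within each condition. They add the differences between lines to the spread, which lowers the count of a draw. They thus show only that the lines as a whole are not interchangeable, and cannot exclude chance for a single comparison. The real values and highest other draws were 2665 and 1 for PV, 1263 and 24 for SST, 2768 and 0 for VIP, and 3608 and 992 for Emx against Gad2.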
